A study of Homo sapiens with 12 samples.

How the data were processed

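Gene expression was measured in 2 established lines of human colorectal cancer cells (HCT116, RKO) 3 days after transfection with a precursor of the microRNA miR-101 or with a negative control duplex, each at 5 nM. Per the labels, the replicates were independent experiments, and each of the 4 groups had 3 of them, which gave 12 arrays. The labels leave open whether control and miR-101 arrays of the same replicate number came from the same experiment. Total RNA had been amplified to Cy3-labelled cRNA and hybridised to 1-colour Agilent expression arrays. The arrays did not measure miR-101 itself, so the labels could not be checked against the level of the microRNA. No array without a transfected duplex was analysed here.

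The deposited scanner files hold spot intensity on a linear scale. Per the file headers they were written by Agilent Feature Extraction 10.7.3.1, and their processed signal is the intensity after the scanner software's own background correction. The authors' series table was compared with these files array by array. Its values matched the processed signal (r = 1 on every array, median log2 difference 0), so it is a linear intensity with no scaling between arrays and no centring, and the column medians ran from 105 to 151. Any normalization that the authors applied after that step is not given in the sources used here.

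The value analysed was log2 of the processed signal minus the array's 75th percentile of it over non-control probes. Control spots and spots marked as outliers by the scanner software (216 to 395 per array) were left out, and repeated spots of a probe were averaged. Each array carried 43118 non-control spots of 34127 probes. Between 61.7% and 81.1% of the spots of an array were well above background, and 0 spots were saturated. The number of arrays limits the precision of every value.

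Probes were named by matching their accession, without its version, to a RefSeq gene table of GRCh38.p14. A symbol was found for 24827 probes (72.7%), which represented 19062 genes, and 9300 probes had no symbol and were counted separately. The file headers name an older genome build, so no coordinates are given. A probe was kept if it was well above background on all 3 arrays of at least 1 group. The probe with the highest mean over all arrays stood for its gene, which left 14770 genes. Of 3549 genes with several kept probes, 18 in HCT116 and 40 in RKO had probes called in opposite directions.

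A gene that was not well above background on any array of a group has only a bound on its change. The bound is written as at least N-fold. It sets the brighter group's mean against the dim group's mean of, per array, the higher of the lowest signal among probes well above background and the probe's own signal. No fold is given where both groups were dim or where the bound was under 1.

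All 12 arrays entered a single linear model with a mean for each group, fitted with limma 3.58.1 (lmFit, then eBayes with a trend) in R 4.3.3. Tables were prepared with Python 3.11.15. Residual degrees of freedom were 8, and the prior added 2.13. The contrasts were miR-101 minus control in HCT116, the same in RKO, the mean of both, and the RKO effect minus the HCT116 effect, called the difference between lines. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. Changes are log2 fold changes ± SE with n = 3 arrays per group, and a negative value means a lower signal after miR-101.

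Gene lists were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 24 lists that had at least 5 genes. Camera with an estimated correlation and fry were run beside it. Fry asks whether the genes of a list move, on balance, in 1 direction, and does not compare them with other genes. List medians and counts cover members with a value on all 12 arrays. The lists held miR-101 targets named in the literature, Polycomb repressive complex 2, genes silenced by EZH2, genes of DNA replication, genes of mitosis, p53 targets, interferon-stimulated genes, Wnt targets, apoptosis genes, autophagy machinery, double-strand break repair, epithelial genes, mesenchymal genes, cholesterol synthesis, the unfolded protein and integrated stress response, glycolysis and hypoxia genes, respiratory chain subunits, ribosomal proteins, early response genes, NF-kappaB targets, microRNA machinery, DNA methylation and chromatin regulators, cytoskeleton and migration genes, and markers of fibroblasts, leukocytes and endothelial cells.

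The model, contrasts, lists above, most alternatives and the rule for naming genes were fixed before the data were examined. A proteasome list, the fits without both HCT116 replicate 3 arrays, on single slides and with probes lacking a symbol, and the list values with a slide block or within slides were added afterwards. The rule took, in each line, the 12 largest changes each way among called genes whose miR-101 arrays all lay beyond all control arrays. It took the 6 largest each way for genes called the same way in both lines and for the difference between lines. In each list it took up to 4 members with the smallest p, and any miR-101 target. List members that moved against the rest of their list, and a few uncalled members, were named after their values were seen.

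The arrays lay on 3 slides of 4 arrays each, scanned on 2 days. Slide 1 was scanned on the first day, and slides 2 and 3 on the second. Slide 1 held HCT116 replicates 1 and 2, slide 2 held HCT116 replicate 3 and RKO replicate 1, and slide 3 held RKO replicates 2 and 3, always with both transfections. The slide was tested as a block (6 residual degrees of freedom), and values were also computed within slides. Because both transfections were balanced on every slide, the block left the size of the changes nearly as it was and altered their errors. HCT116 arrays with the same replicate number deviated together from their group means (r = 0.60, 0.73 and 0.87 across genes for numbers 1, 2 and 3). Each control array correlated best with the miR-101 array of its own number, which was not asked of the miR-101 arrays. For numbers 1 and 2, which share slide 1, the control array's highest correlation with another number was 0.56 and 0.61. Much of the deviation is thus shared by numbers 1 and 2. Deviations from a group mean balance out, so number 3 standing apart would by itself make numbers 1 and 2 deviate together. Number 3 is also alone among HCT116 arrays on slide 2, so these correlations cannot tell whether the slide was the cause. The replicate number was also fitted as a block, but pairing by number is not separated from the slide.

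Replicates of a group correlated at r = 0.971 to 0.997 across genes. The median SD of a gene between replicates was 0.187 and 0.182 in the HCT116 control and miR-101 groups, and 0.0680 and 0.0593 in the RKO control and miR-101 groups. The single spread per gene in the model understates this spread in HCT116 and overstates it in RKO for a typical gene. The first principal component, which separated the cell lines, held 87.1% of the variance. The second, 5.71%, separated the HCT116 replicate 3 arrays from the other HCT116 arrays, and the third, 3.02%, separated miR-101 from control.

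The procedure was tested on simulated data with 200 changed genes among 14720. In HCT116 it called 37.3%, 65.7% and 86.4% of genes changed by 0.5, 1 and 2 on the log2 scale, and in RKO 32.8%, 74.6% and 93.9%. It called 0.0620% of unchanged genes in HCT116 and 0.0482% in RKO. For the difference between lines it called 84.8% of genes that differed by 2. The simulated noise was independent between arrays, with 1 SD per gene for all groups and no slide or replicate pattern. Far fewer genes changed than were called on the real arrays, so these rates do not carry over to them.

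Alternatives were another background correction and normalization, other filters and probe rules, a floor of 8, fits without trend, fits of 1 line alone, blocks, and leaving out each array in turn. The planned background correction used the mean spot signal, which was not analysed here, so normexp (offset 50) was run on the median spot and background signals and followed by quantile normalization. The planned search for miR-101 seed sites needed 3' UTR sequences, which were not used here.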

Results

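The data were 12 expression arrays, with 3 control and 3 miR-101 transfections of each of the HCT116 and RKO colorectal cancer lines, harvested 3 days after transfection with 5 nM of duplex. The comparisons ask which transcripts changed with miR-101 in each line, which changed in both, and which changed differently. After filtering, 14770 genes were tested.

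In HCT116, transcripts of many genes named in the literature as miR-101 targets were lower after miR-101. STMN1, which encodes the microtubule destabiliser stathmin, changed by -2.15 ± 0.13 on the log2 scale (adjusted p = 5.2e-06), although a second, dimmer STMN1 probe gave 0.41. RAB5A, a small GTPase of early endosomes, changed by -1.36 ± 0.08, SUB1 by -0.78 ± 0.05, and the GTPase RAC1 by -0.67 ± 0.04. EZH2, the methyltransferase of Polycomb repressive complex 2, changed by -0.62 ± 0.08 (adjusted p = 0.00034). Of the 29 measured targets, 16 fell, 1 rose and 12 were not called (17 fell and 1 rose when adjusted over the list alone). The target that rose was ROCK2, a kinase of the actin cytoskeleton, at 0.62 ± 0.10. The median of the list was -0.60, and its camera adjusted p was 6.0e-08, against an adjusted p of 0.072 with an estimated correlation. The median was -0.60 with the slide as a block (adjusted p = 1.2e-06), -0.58 within slide 1 and -0.59 within slide 2. With the slide as a block and an estimated correlation, the camera adjusted p was 0.37.

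Outside that list, the largest falls in HCT116 included NAT16, which was at least 3.67-fold lower after miR-101 (adjusted p = 5.8e-05), and MTMR2, a lipid phosphatase of the myotubularin family, at -1.94 ± 0.08. FAM3C, which encodes a secreted protein, changed by -1.87 ± 0.10, and NAP1L5 by -1.84 ± 0.09. Several of the largest rises were in genes that were not well above background on any HCT116 control array. CALB1, the calcium-binding protein calbindin, was at least 7.52-fold higher (adjusted p = 0.00019), TSPAN8, a tetraspanin, at least 2.84-fold higher (adjusted p = 0.00084), and ZFP42 at least 3.00-fold higher (adjusted p = 0.00022). SAA1 and SAA2, acute-phase serum amyloid genes, were at least 5.93-fold and 1.80-fold higher (adjusted p = 8.7e-05 and 0.00012), but they are near-identical copies and cross-hybridisation leaves each uncertain. TM4SF1 was at least 2.65-fold higher, while its other probe gave -0.24. Among genes seen in both HCT116 groups, the keratin gene KRT80 rose by 3.34 ± 0.52 and the cytokine gene IL7 by 2.16 ± 0.19.

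In HCT116, camera at the preset correlation also called interferon-stimulated genes, cholesterol synthesis genes, NF-kappaB targets and p53 targets as higher than other genes. With an estimated correlation none of these calls held (adjusted p = 0.081, 0.58, 0.21 and 0.85). Of 29 interferon-stimulated genes, 11 rose, 1 fell and 17 were not called (13 and 1 when adjusted over the list alone). CMPK2 rose by 1.17 ± 0.11, IFIT2 by 1.07 ± 0.12 and the transcription factor gene IRF7 by 0.63 ± 0.10. The list median was 0.37, with an adjusted p of 0.0022 and an adjusted p of 0.081 with an estimated correlation. A block for slide left it at 0.37 (adjusted p = 0.0082), and it was 0.30 within slide 1 and 0.37 within slide 2.

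Of 24 cholesterol genes in HCT116, 13 rose, 4 fell and 7 were not called (14 and 4 when adjusted over the list alone). The isomerase gene IDI1 rose by 0.79 ± 0.10, NSDHL by 0.60 ± 0.07, HSD17B7 by 0.59 ± 0.08 and FDPS by 0.36 ± 0.05. Those that fell included TM7SF2 (-0.66 ± 0.15), LSS (-0.37 ± 0.08, with 0.29 at its other probe) and PMVK (-0.32 ± 0.07). The median was 0.33, with an adjusted p of 0.0064 and an adjusted p of 0.58 with an estimated correlation. With the slide as a block it was 0.33 (adjusted p = 0.035), and it was 0.27 within slide 1, whose 4 arrays alone gave an adjusted p of 0.13, and 0.41 within slide 2. Of 15 NF-kappaB targets, 8 rose, 1 fell and 6 were not called (9 and 1 when adjusted over the list alone). RELB, a subunit of NF-kappaB, rose by 0.66 ± 0.11, the cytokine gene LIF by 0.57 ± 0.07, the adhesion gene ICAM1 by 0.46 ± 0.09 and NFKB1 by 0.31 ± 0.05, and TNFAIP2 fell (-0.23 ± 0.06). The median was 0.46, with an adjusted p of 0.0028 and an adjusted p of 0.21 with an estimated correlation. A block for slide left it at 0.46 (adjusted p = 0.010), and it was 0.32 within slide 1 and 0.66 within slide 2.

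Of 27 p53 targets in HCT116, 11 rose, 3 fell and 13 were not called (12 and 3 when adjusted over the list alone). The death receptor gene FAS rose by 1.16 ± 0.15, the p53 antagonist MDM2 by 0.71 ± 0.10 and FDXR by 0.49 ± 0.05. The members that fell were ZMAT3 (-0.92 ± 0.13), TP53INP1 (-0.52 ± 0.07, with -0.05 at its other probe) and TRIAP1 (-0.35 ± 0.10). CDKN1A, the cell cycle inhibitor p21, was not called (0.19 ± 0.38). The median was 0.27, with an adjusted p of 0.014 and an adjusted p of 0.85 with an estimated correlation. With the slide as a block it was 0.27 (adjusted p = 0.0098), and it was 0.33 within slide 1 and 0.44 within slide 2. The call was lost without HCT116 control replicate 2 (median 0.16, adjusted p = 0.071) and without HCT116 miR-101 replicate 3 (median 0.13, adjusted p = 0.12), and fry gave an adjusted p of 0.053.

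In all, 3588 genes were called in HCT116, 1787 higher and 1801 lower, and 130 of the higher and 179 of the lower ones changed at least 2-fold. With the slide as a block 6430 genes were called, among them all 3588, and with the replicate number as a block 6501; slide 1 alone gave 2384. The called genes kept their direction within slide 1 (3581 of 3581 with a value) and slide 2 (3587 of 3587), although each slide had contributed to the calls. Scaling to the median called 571 genes (182 higher, 389 lower), the unscaled series values gave 1150 (440 higher, 710 lower), and the 6 HCT116 arrays by themselves gave 1380. The fit of those 6 arrays kept 1304 of the 3588 calls. Median scaling also ended the HCT116 calls of RAC1, ROCK2, IDI1, NSDHL, HSD17B7, FDPS, RELB, LIF, ICAM1, NFKB1, MDM2, FDXR and TP53INP1, and averaging over probes those of LIF and TP53INP1, with no change of direction.

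In RKO, many of the literature targets of miR-101 were also lower. STMN1 changed by -1.94 ± 0.13, with 0.24 at its other probe, RAB5A by -1.67 ± 0.08, SUB1 by -1.29 ± 0.05, RAC1 by -0.61 ± 0.04 and EZH2 by -0.63 ± 0.08 (adjusted p = 0.00023). Of 29 targets, 15 fell, 2 rose and 12 were not called (18 and 3 when adjusted over the list alone). The targets that rose were JAK2, a cytokine receptor kinase, at 0.44 ± 0.08, and KDM4C, a histone demethylase, at 0.23 ± 0.06. The call of KDM4C was lost without RKO control replicate 1 or 3 or any single RKO miR-101 array (adjusted p from 0.057 to 0.087). The median was -0.46, with an adjusted p of 4.6e-05 and an adjusted p of 0.15 with an estimated correlation. A block for slide left it at -0.46 (adjusted p = 0.00055, and adjusted p = 0.40 with an estimated correlation), and it was -0.56 within slide 2 and -0.46 within slide 3.

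Other large falls in RKO were those of SLC9A9, a sodium-proton exchanger, at least 4.20-fold (adjusted p = 0.00018), GLI1, the transcription factor of Hedgehog signalling, at -2.48 ± 0.34, KLF2, a Krüppel-like transcription factor, at -2.26 ± 0.14, MTMR2 at -2.23 ± 0.08 and POMP, the proteasome maturation protein, at -1.86 ± 0.09. Several of the largest rises were in genes that no RKO control array showed well above background. The chemokine gene CXCL3 was at least 3.42-fold higher (adjusted p = 0.00056), MYO1D at least 3.27-fold (adjusted p = 5.4e-06, with a log2 change of 0.72 at its other probe), IFI44 at least 2.93-fold (adjusted p = 0.00070), UBA7, the activating enzyme for ISG15, at least 2.71-fold (adjusted p = 7.7e-05) and CYP27A1, a sterol hydroxylase, at least 2.51-fold (adjusted p = 0.0029). CTAG1A was at least 3.14-fold higher, but near-identical copies of it leave this uncertain. IL22RA1, a subunit of the interleukin-22 receptor, rose by 2.80 ± 0.13 and DIRAS3, a small GTPase of the Ras family, by 2.50 ± 0.12.

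Of 27 p53 targets in RKO, 17 rose, 1 fell and 9 were not called (17 and 1 when adjusted over the list alone). TP53INP1 rose by 1.98 ± 0.07, the antiproliferative gene BTG2 by 1.28 ± 0.06, the DNA damage sensor DDB2 by 1.19 ± 0.08 and FDXR by 0.99 ± 0.05. ZMAT3 fell by 0.43 ± 0.13, and CDKN1A was not called (-0.03 ± 0.38). The median was 0.66, with an adjusted p of 1.8e-08 and an adjusted p of 0.37 with an estimated correlation. With the slide as a block it was 0.66 (adjusted p = 5.0e-08), and it was 0.68 within slide 2 and 0.67 within slide 3. Of 29 interferon-stimulated genes, 14 rose, 1 fell and 14 were not called (15 and 1 when adjusted over the list alone), with IFIT2 at 2.40 ± 0.12 and IFIT1 at 2.12 ± 0.20. HERC5 was at least 1.07-fold higher (adjusted p = 8.8e-06), and the ubiquitin-like modifier ISG15 changed by -0.49 ± 0.04. The median was 0.44, with an adjusted p of 1.1e-05 and an adjusted p of 0.034 with an estimated correlation. A block for slide left it at 0.44 (adjusted p = 5.0e-06, and adjusted p = 0.15 with an estimated correlation), and it was 0.46 within slide 2 and 0.64 within slide 3.

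Of 27 genes of the unfolded protein and integrated stress response in RKO, 12 fell, 1 rose and 14 were not called (14 and 1 when adjusted over the list alone). The median was -0.40, with an adjusted p of 0.0013 and an adjusted p of 0.37 with an estimated correlation. MANF, a secreted protein of the endoplasmic reticulum, changed by -0.74 ± 0.07, the transcription factor genes CEBPB by -0.67 ± 0.05, ATF4 by -0.57 ± 0.07 and XBP1 by -0.53 ± 0.06, whereas HSPA5, the main chaperone of the endoplasmic reticulum, rose by 0.35 ± 0.09. With the slide as a block the list median was -0.40 (adjusted p = 0.0020), and it was -0.40 within slide 2 and -0.39 within slide 3.

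In all, 4317 genes were called in RKO, 2053 higher and 2264 lower, and 311 of the higher and 164 of the lower ones changed at least 2-fold. The majority turned with the scaling, to 2043 higher and 1656 lower with quantile normalization, 1830 and 1453 with normexp, and 1005 and 751 in the unscaled series values. The slide block called 7150 genes, among them all 4317, and slide 3 alone gave 7692. The called genes kept their direction within slide 2 (4315 of 4317) and slide 3 (4316 of 4316 with a value). Scaling to the median called 1039 genes, the unscaled series values gave 1756, the 6 RKO arrays by themselves 7737, and the fit without both HCT116 replicate 3 arrays 6873. Median scaling ended the RKO calls of RAC1, JAK2, ISG15 and XBP1, with no change of direction.

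**Figure D1:**
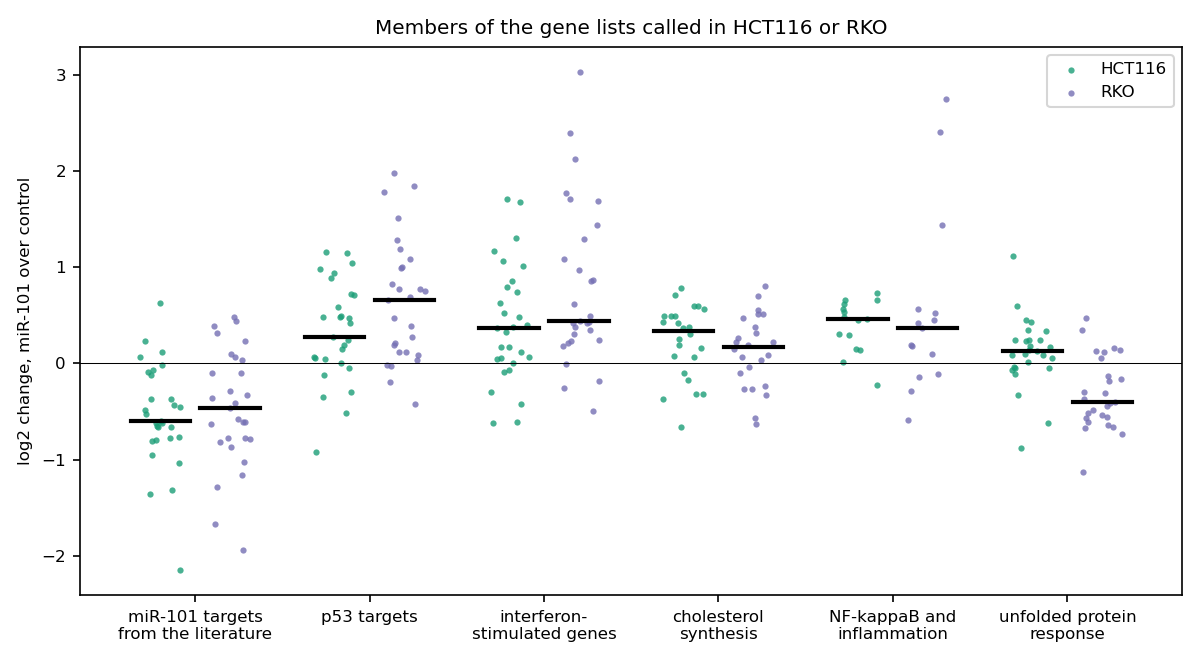
Log2 change of each measured member (points) of the gene lists called in HCT116 or RKO, miR-101 over control, from means of 3 arrays per group. Most miR-101 targets lie below 0 in both lines (median -0.60 in HCT116 and -0.46 in RKO), and most interferon-stimulated genes lie above 0 (0.37 and 0.44).

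Many genes changed the same way in both lines. The largest shared falls after miR-101 were those of MTMR2 (-1.94 ± 0.08 in HCT116 and -2.23 ± 0.08 in RKO), STMN1 and GLI1 (-1.57 ± 0.34 and -2.48 ± 0.34), followed by NOTCH4, a Notch receptor (-1.73 ± 0.36 and -1.79 ± 0.36), and DHTKD1, a mitochondrial dehydrogenase subunit (-1.76 ± 0.12 and -1.68 ± 0.12). NAT16 was called lower in both lines but was not well above background on any RKO array, so no fold is given for RKO. The largest shared rises included IFI44 (1.71 ± 0.46 in HCT116), PRDM1, a transcriptional repressor (1.58 ± 0.35 and 2.43 ± 0.35), IFIT2, IL1RAP, the accessory protein of the interleukin-1 receptor (1.35 ± 0.17 and 2.08 ± 0.17), and LAMP3 (1.36 ± 0.13 and 2.02 ± 0.13). The growth factor gene FGF1 was called higher in both lines, but its controls were dim and its bound was under 1. The RKO call of NAT16 was lost with a floor of 8 (adjusted p = 0.24) and on slide 3 alone (adjusted p = 0.11). The HCT116 call of IFI44 was lost without HCT116 control replicate 1 (1.67, adjusted p = 0.062) and without HCT116 miR-101 replicate 3 (1.43, adjusted p = 0.070).

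Among the literature targets, EZH2, STMN1, RAB5A, SUB1, RAC1, the lamin gene LMNB1 (-0.81 ± 0.07 and -0.82 ± 0.07), the Mediator kinase CDK8 (-0.95 ± 0.13 and -1.16 ± 0.13), the autophagy protease ATG4D (-1.04 ± 0.08 and -0.87 ± 0.08) and the transcription factor ZEB1 (-0.53 ± 0.10 and -0.61 ± 0.10) fell in both lines. MCL1, which blocks apoptosis, also fell in both (-0.66 ± 0.17 and -1.02 ± 0.17), but its HCT116 call was lost without HCT116 miR-101 replicate 1 (-0.62, adjusted p = 0.060) or replicate 2 (-0.57, adjusted p = 0.068). Median scaling ended the HCT116 calls of CDK8, MCL1, ZEB1 and IFI44 and the RKO calls of MCL1 and ZEB1, and normexp the HCT116 calls of ZEB1, IFI44 and FGF1, with no change of direction. For the mean of both lines, 19 of the 29 targets fell, 3 rose and 7 were not called (19 and 3 when adjusted over the list alone). The median was -0.47 (adjusted p = 5.6e-07, and 0.059 with an estimated correlation). With the slide as a block its adjusted p was 9.3e-06, and 0.19 with an estimated correlation as well. The interferon list had a mean effect with median 0.47 (adjusted p = 1.8e-05; adjusted p = 0.043 with an estimated correlation, and 0.19 with that and the slide as a block) and the p53 list one with median 0.37 (adjusted p = 4.8e-07; adjusted p = 0.39 with an estimated correlation). The NF-kappaB list (median 0.33, adjusted p = 0.0021) and the cholesterol list (median 0.26, adjusted p = 0.025) were also called. With an estimated correlation their adjusted p was 0.21 and 0.67, and with the slide as a block the cholesterol list had an adjusted p of 0.069.

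Of the genes called, 983 were lower in both lines, where independent lists would share 276, and 817 were higher in both, where 248 would be shared (one-sided Fisher's exact test, p = 2.3e-280 for the higher genes and smaller for the lower ones; genes are not independent). Opposite calls were fewer than independent lists would give, with 134 genes lower in HCT116 and higher in RKO against 250, and 127 the other way against 274. Across all 14770 genes, the changes in the lines correlated at r = 0.37 (Spearman 0.38), a correlation across genes, which are not independent replicates. The lines shared no control arrays, but both contrasts took their errors from the same spread per gene. A gene with a small spread was thus more easily called in both lines, which the expected overlaps and Fisher's test ignore. With the spread taken from each line alone, 1380 genes were called in HCT116, 7737 in RKO and 916 the same way in both. No expected overlap was computed for those fits. The mean effect was called for 4995 genes, 2452 higher and 2543 lower, and for 7758 with the slide as a block. Scaling to the median gave 1623 for the mean effect and 240 genes called the same way in both lines, against 1800; the unscaled series values gave 2590 and 481.

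**Figure D2:**
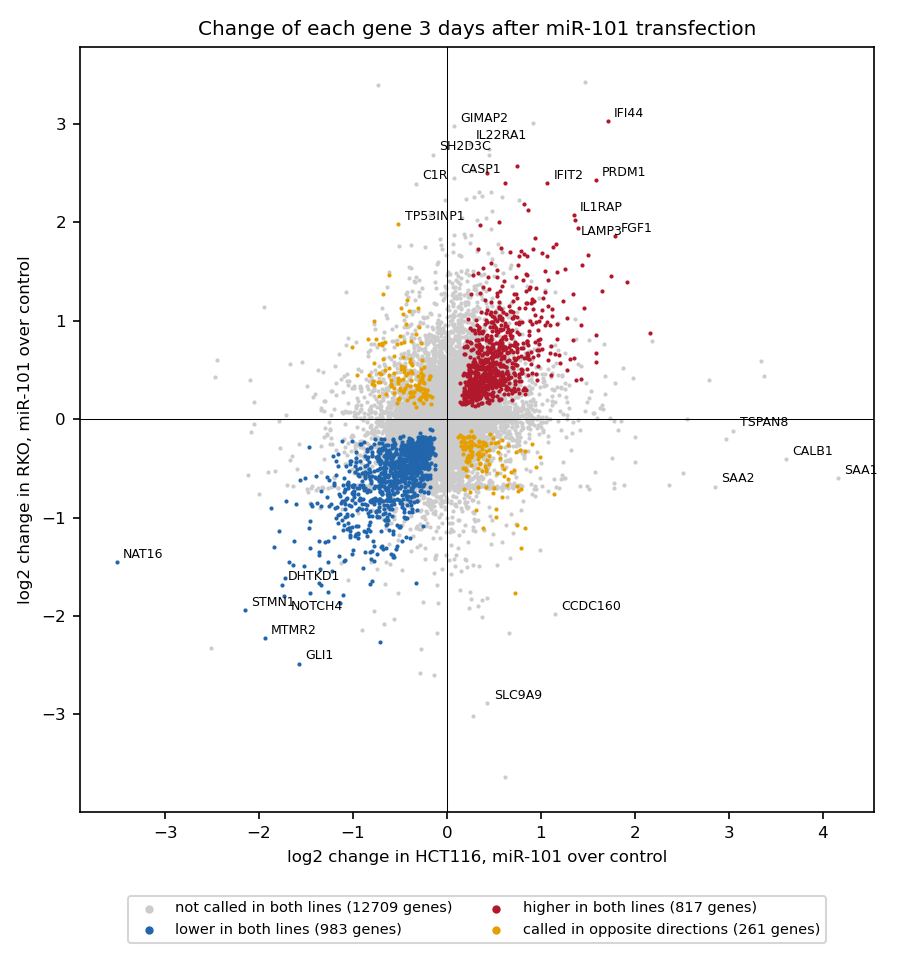
Log2 change of each of 14770 genes in HCT116 (horizontal axis) against RKO (vertical axis), miR-101 over control, coloured by the direction of the calls. The 983 genes lower in both lines and the 817 higher in both outnumber the 134 and 127 genes called in opposite directions.

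**Figure D3:**
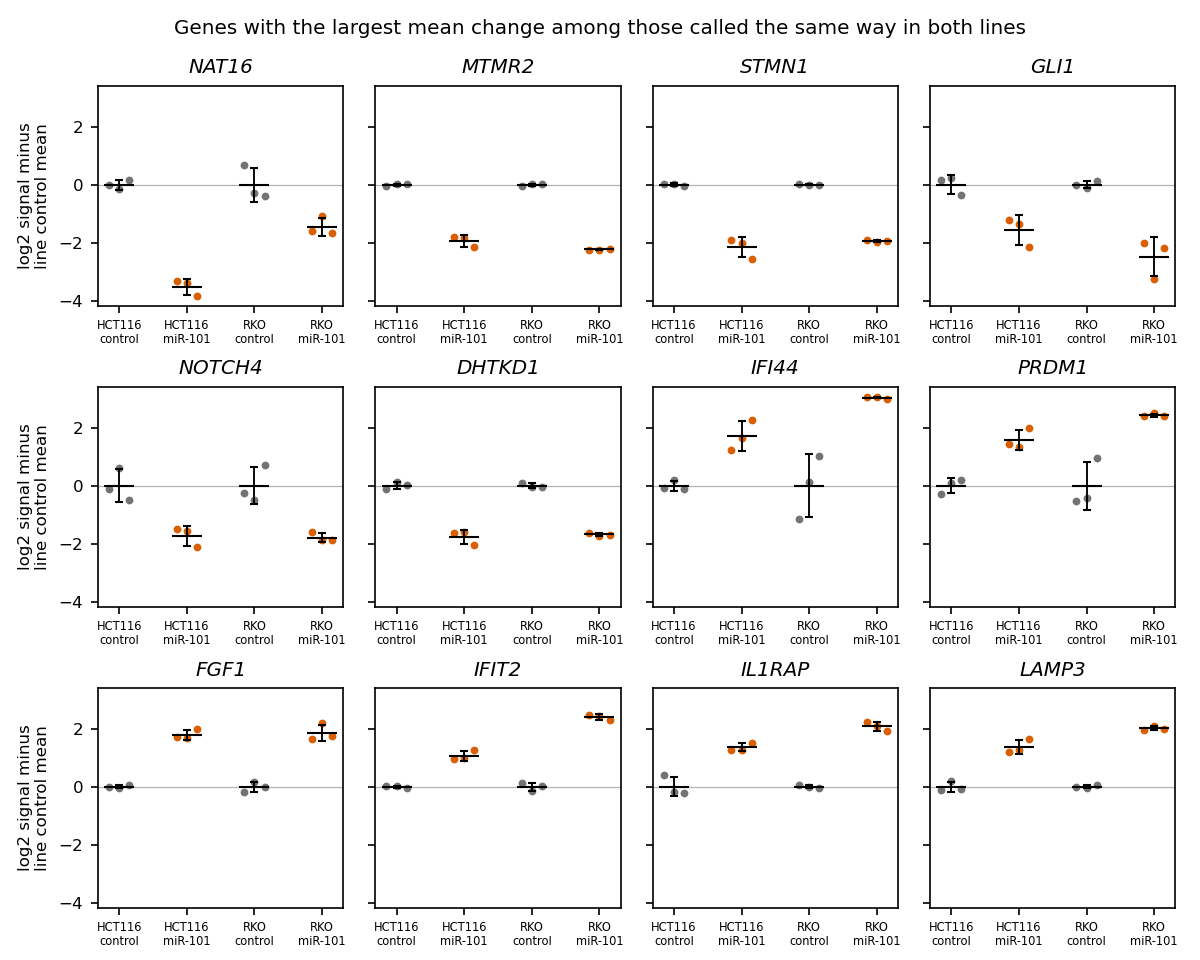
Log2 signal of each array (points) minus the control mean of its line, for the 12 genes with the largest mean change among those called the same way in both lines, with the mean of each group of 3 arrays. The miR-101 arrays of MTMR2 and DHTKD1 lie below, and those of IFIT2 and LAMP3 above, the control arrays of both lines.

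Some genes responded differently in the lines, by the test of the difference itself. SAA1, SAA2, CALB1 and TSPAN8 rose in HCT116 and were not well above background on any RKO or HCT116 control array (adjusted p of the difference 0.00082, 0.00074, 0.0019 and 0.0092). SLC9A9 fell in RKO and was not well above background on any RKO miR-101 or HCT116 control array (adjusted p = 0.0020). The sizes of these differences rest on background signal and are not given. In the other direction, IL22RA1 differed, RKO minus HCT116, by 2.56 ± 0.19 on the log2 scale and the complement protease gene C1R by 2.72 ± 0.23 (1.63 in RKO and -0.11 in HCT116 at its other probe). GIMAP2, SH2D3C and CASP1, the inflammatory caspase, were also called (adjusted p = 0.0034, 0.00089 and 0.011), with no size given because no RKO control array showed them well above background. TP53INP1, a p53 target, fell in HCT116 and rose in RKO, with a difference of 2.50 ± 0.10 (adjusted p = 3.4e-06).

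Of the lists, camera at the preset correlation called p53 targets and stress response genes for the difference, and neither call held with an estimated correlation (adjusted p = 0.76 and 0.68). For p53 targets, 8 of 27 changed more in the upward direction in RKO, 0 in the downward and 19 were not called (12 and 0 when adjusted over the list alone), with BTG2 at 1.22 ± 0.08, DDB2 at 0.72 ± 0.11 and RRM2B, a ribonucleotide reductase subunit, at 0.63 ± 0.07. The median difference was 0.27 (adjusted p = 0.00011; adjusted p = 0.0012 with the slide as a block). For the stress response, 11 of 27 differed downward in RKO, 0 upward and 16 were not called (12 and 0 when adjusted over the list alone), with MANF at -0.98 ± 0.10, ATF4 at -0.75 ± 0.09, PSAT1, an enzyme of serine synthesis, at -0.72 ± 0.09 and XBP1 at -0.70 ± 0.08. The median difference was -0.34 (adjusted p = 3.8e-05; adjusted p = 1.2e-05 with the slide as a block). The interferon list was not called for the difference (median 0.28, adjusted p = 0.12) but was with the slide as a block (adjusted p = 0.035), though not with an estimated correlation as well (adjusted p = 0.61). Slide 2 was the only slide with arrays of both lines, and it held 1 array of each group. All RKO arrays were scanned on the second day, but HCT116 replicates 1 and 2 on the first.

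In all, 2155 genes differed between the lines, 1071 with a higher and 1084 with a lower change in RKO, and 382 of them differed at least 2-fold. The slide block called 5050, among them all 2155. Scaling changed both the count and the split. Quantile normalization called 1721 (1137 higher, 584 lower), normexp with quantile normalization 1536 (1016 and 520), the unscaled series values gave 369 (273 and 96) and median scaling 103 (70 and 33). Median scaling moved the median difference of all genes to -0.11, and under it the median difference was 0.20 for the p53 list and -0.41 for the stress response. It ended the difference calls of BTG2, DDB2, RRM2B, MANF, ATF4, PSAT1, XBP1 and CASP1, averaging over probes that of DDB2, and normexp that of TSPAN8, with no change of direction.

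Camera at the preset correlation did not call the other lists in either line. Fry, which asks only whether a list moves on balance, called several of them. In HCT116 these were Polycomb repressive complex 2, DNA methylation and chromatin regulators, respiratory chain and microRNA machinery (lower) and epithelial and glycolysis and hypoxia genes (higher). In RKO they were Polycomb repressive complex 2, genes silenced by EZH2, mitosis, double-strand break repair, respiratory chain and DNA methylation and chromatin regulators (lower) and Wnt targets, mesenchymal genes and NF-kappaB targets (higher). The fry adjusted p of Polycomb repressive complex 2 was 0.00017 in HCT116 and 0.0017 in RKO. In HCT116 the microRNA machinery and the glycolysis and hypoxia list had a median of the opposite sign to fry, and in RKO Polycomb repressive complex 2 did. Median log2 changes in HCT116 and RKO were -0.12 and 0.01 for Polycomb repressive complex 2, 0.09 and -0.11 for genes silenced by EZH2, -0.07 and -0.07 for DNA replication, and 0.02 and -0.03 for mitosis. They were -0.06 and 0.27 for Wnt targets, 0.01 and -0.02 for apoptosis genes, 0.06 and 0.02 for autophagy machinery, and 0.04 and -0.11 for double-strand break repair. They were 0.05 and -0.02 for epithelial genes, 0.15 and 0.09 for mesenchymal genes, -0.01 and -0.17 for glycolysis and hypoxia, -0.04 and -0.10 for the respiratory chain, and 0.10 and -0.04 for ribosomal proteins. They were 0.06 and -0.24 for early response genes, 0.01 and -0.09 for microRNA machinery, -0.07 and -0.08 for DNA methylation and chromatin regulators, and 0.03 and 0.01 for cytoskeleton and migration genes. With the slide as a block the ribosomal list was called in HCT116 (adjusted p = 0.035), but not with an estimated correlation (adjusted p = 0.86), and its median was 0.06 within slide 1 and 0.19 within slide 2. In RKO, NF-kappaB targets (median 0.36, adjusted p = 0.057) and cholesterol genes (0.17, adjusted p = 0.36) were not called by camera, nor was the stress response in HCT116 (0.13, adjusted p = 0.30). The unadjusted camera p of NF-kappaB targets in RKO was 0.012, and it was 0.0068 with quantile, 0.0018 with median and 0.0014 with normexp scaling, each of which called 5 rather than 4 lists in RKO. Leukocyte markers had medians of 0.20 and 0.10, with 0 of 9 called in HCT116 and 1 of 9 in RKO, and only 3 of 12 fibroblast and 4 of 10 endothelial markers could be tested. Of these, ACTA2, an actin gene, rose in both lines (0.60 ± 0.11 and 0.71 ± 0.11), and the other fibroblast and endothelial markers tested were not called.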

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

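Of the tests in this part, the correlation on slide 2 was chosen after the result was seen. The difference between lines was picked out because the miR-101 effects of RKO and HCT116 differed by a test of the difference itself, for 2155 genes. The genes named by the fitted difference of log2 changes, RKO minus HCT116, were SAA1 (-4.76), CALB1 (-4.01), SAA2 (-3.53), SLC9A9 (-3.32), TSPAN8 (-3.17) and CCDC160 (-3.13) in 1 direction, and GIMAP2 (2.91), SH2D3C (2.84), C1R (2.72), IL22RA1 (2.56), TP53INP1 (2.50) and CASP1 (2.38) in the other. All of these but C1R, IL22RA1 and TP53INP1 were not well above background on any array of at least 1 group, so their fitted values and their order rest partly on background signal and are not measured sizes. The call of CCDC160 (adjusted p = 0.036) was lost without any single HCT116 array or any single RKO miR-101 array, with values from -3.29 to -3.03 and adjusted p from 0.054 to 0.084. The p53 targets (median difference 0.27) and the stress response genes (-0.34) were picked out by camera on the same contrast, and neither call held with an estimated correlation (adjusted p = 0.76 and 0.68). Among 5149 probes without a gene symbol, which the comparisons above do not use, 244 were called in HCT116 (92 higher, 152 lower) and 416 in RKO (186 higher, 230 lower).

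Other splits of the arrays were tried for each count. In HCT116, 1 of the 10 splits of the 6 arrays into 3 and 3, the real one, gave as many as 3588 called genes. The highest other split gave 1319, and it set control 1, control 3 and miR-101 3 against the rest. Each of the other splits that part all 3 same-number pairs, as the real split does, gave 0 genes. In RKO, 1 of 10 splits gave as many as 4317, and the highest other gave 0. For the difference, 1 of 10 splits of the miR-101 minus control differences gave as many as 4588 genes, the count of that paired fit, and the highest other gave 0. A set of 10 splits is too small for a share under 0.05. For the mean effect, 1 of 100 splits within both lines gave as many as 4995 genes, and the highest other gave 2216. This excludes chance only among splits that treat the arrays of a line as exchangeable, which ignores the pairs and the slides.

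The miR-101 effect on p53 targets was higher in RKO than in HCT116 by a median of 0.27. An effect of scaling as the whole cause is argued against by the medians under quantile, median and normexp scaling, of which the lowest was 0.20. A single gene is argued against by the camera p without TP53INP1, 9.64e-05, although with an estimated correlation it was 0.20, and 0.15 for the whole list, so correlation among the members stays open. Both transfections are balanced on every slide, so a slide difference common to them cancels in these contrasts. The slide block therefore could not move the median, and its camera p of 0.000103 decides nothing. A miR-101 effect that itself differed between slides stays open too. Medians of the list within slides were 0.33 and 0.44 in HCT116 and 0.68 and 0.67 in RKO, and a difference between the lines themselves also stays open.

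Of 29 interferon-stimulated genes, 11 rose in HCT116 and 14 in RKO, with medians of 0.37 and 0.44. With an estimated correlation the adjusted p of the list was 0.081 in HCT116 and 0.034 in RKO, and 0.15 in RKO with the slide as a block, so the list call is not firm. Dim probes are argued against as the whole cause, since the 24 members well above background on all 12 arrays had medians of 0.38 in HCT116 and 0.43 in RKO. Scaling is argued against too, since the lowest median in a line under quantile, median and normexp scaling was 0.31. A response to the RNA duplex itself, which could differ between miR-101 and the control duplex, cannot be told apart from an effect of miR-101, because 0 arrays without a transfected duplex and no other duplex were compared.

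The HCT116 replicate 3 arrays stood apart from replicates 1 and 2. Slide 2, which held both of them and RKO replicate 1, is a candidate explanation, since their deviation correlated across genes with that of RKO replicate 1 (r = 0.364), against -0.331 and -0.325 for HCT116 replicates 1 and 2, although genes are not independent and the deviations of 3 replicates constrain one another. RKO replicate 1 deviated much less, with a median absolute deviation of 0.0703. Dim probes stay open, since the median absolute deviation was 0.180 in the brightest and 0.522 in the dimmest of 3 brightness classes, a ratio of 0.345 that lay between the bounds set in advance. No biological explanation was tested, and a difference between the experiments cannot be separated from the slide. The day of scanning cannot be separated either. HCT116 replicates 1 and 2 were scanned on the first day, and HCT116 replicate 3 on the second with all RKO arrays.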

How the results depend on the processing

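The fits without both HCT116 replicate 3 arrays, on slide 1 or 3 alone and with probes lacking a symbol were chosen after the data were seen; the other alternatives were planned. Of the 165 pairs of a named gene and a comparison, 141 were called. Of these 141, 0 reversed direction in any alternative that gave them a value, and 0 of the called lists did. For uncalled pairs, a reversal was counted only where the alternative called them, and none was found. Other changes of their direction were not counted. The filter for all 12 arrays, the 6 arrays of a line and the single slides did not cover all of the pairs. Leaving out each array in turn gave 2953 to 3740 genes in HCT116, 3268 to 5005 in RKO, 4300 to 5342 for the mean, 1447 to 2592 for the difference and 1422 to 1853 called the same way in both lines, with 5 to 6 lists in HCT116 and 4 to 5 in RKO, and 128 of the 141 called pairs kept their call in all 12 such fits. Median scaling gave 571 genes in HCT116, 1039 in RKO, 1623 for the mean, 103 for the difference and 240 in both lines, and ended 47 named calls. The unscaled series values gave 1150, 1756, 2590, 369 and 481 and ended 26 named calls. The slide as a block gave 6430, 7150, 7758, 5050 and 3270, and the replicate number as a block 6501, 7190, 7886, 5075 and 3277; each ended 0 named calls. In RKO same-number arrays deviated together less (r = 0.303, 0.163 and 0.0685). Those numbered 1 also share slide 2. Those numbered 2 and 3 all lie on slide 3, so there only the number sets the pairs apart. RKO control array 3 correlated better with a miR-101 array of another number (r = 0.0946) than with that of its own. The 6 arrays of a line by themselves gave 1380 genes in HCT116, 7737 in RKO and 916 in both, and ended 13 named calls. They kept 36.3% of the calls in HCT116 and 97.7% in RKO, in the same direction. These fits take the spread from 1 line alone, and it was larger between HCT116 than between RKO replicates. Without both HCT116 replicate 3 arrays, 6873 genes were called in RKO and 4028 for the difference, and 5 named calls ended. Slide 1 alone gave 2384 genes in HCT116 and slide 3 alone 7692 in RKO, each from 2 arrays per group. Requiring a change of at least 2-fold left 309, 475, 251, 382 and 79 by construction. For the other shifts the cause was not tested. Camera with an estimated correlation called 0 lists in HCT116, where fry called 10, and 1 in RKO, where fry called 13. Normexp and quantile normalization, other filters and probe rules, the floor of 8 and the fit without trend kept each count within 1.5 times, with up to 1 list more than in the chosen fit. Similar counts did not mean the same genes. Normexp kept 78.7% of the calls in HCT116, 67.9% in RKO and 54.1% for the difference, in the same direction. Quantile normalization alone kept 86.9%, 76.2% and 64.1%, and median scaling 15.7%, 23.0% and 4.78%. Signal near background limits the fold of dim genes. The search for seed sites was not run, because it needed 3' UTR sequences that were not used here.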

Other observations

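The proteasome list and its test were chosen after the fall of POMP was seen, and the single genes below were picked after their values were seen. All changes are log2, miR-101 minus control, with n = 3 arrays per group.

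Within lists that were not called, single members were called in the same direction in both lines, though not always by the same amount. In Polycomb repressive complex 2, RBBP7, a histone-binding subunit, fell by 0.65 ± 0.05 in HCT116 and by 0.82 ± 0.05 in RKO, and AEBP2 by 0.59 ± 0.09 and 0.50 ± 0.09, whereas JARID2 rose by 0.43 ± 0.13 and 0.51 ± 0.13 (adjusted p = 0.035 and 0.013). SUZ12, the scaffold subunit, was not called (0.01 ± 0.09 and -0.05 ± 0.09). Among epithelial genes, of which 6 rose and 2 fell for the mean effect, the keratin gene KRT18 rose by 1.19 ± 0.09 and 0.65 ± 0.09 (difference -0.54 ± 0.12, called), and the desmosome gene DSP by 0.78 ± 0.09 and 0.47 ± 0.09. The spindle checkpoint gene MAD2L1 fell by 0.68 ± 0.10 and 1.32 ± 0.10 (difference -0.64 ± 0.15, called), the ATP synthase subunit gene ATP5F1B by 0.84 ± 0.14 and 1.12 ± 0.14, and the repair gene BRCA1 by 0.40 ± 0.05 and 0.46 ± 0.05.

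Other genes moved in opposite directions, with a called difference. SLC2A1, the main glucose transporter of many cells, rose by 0.59 ± 0.07 in HCT116 and fell by 0.79 ± 0.07 in RKO (difference -1.38 ± 0.09), and the phosphatase gene DUSP5 rose by 1.14 ± 0.15 and fell by 0.76 ± 0.15 (difference -1.90 ± 0.21). The tight junction gene CLDN3 fell by 0.47 ± 0.10 in HCT116 and rose by 1.07 ± 0.10 in RKO (difference 1.54 ± 0.15).

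A hypothesis was that genes that fell are direct targets of the transfected miRNA and so are shared between lines more often than genes that rose. It predicted a ratio of the observed over expected overlaps of at least 1.3. The ratio was 1.08 (95% bootstrap interval 1.02 to 1.15 over 1000 resamples of genes), below the predicted size. The interval holds the calls fixed and treats genes as independent, so it leaves out the spread between arrays. With the slide as a block the overlaps were 2.15 times the expected for lower and 2.07 times for higher genes. Other scalings were not tried for the ratio, so the predicted size is argued against in these fits only. A second hypothesis was that proteasome subunit genes rise together where POMP, the proteasome maturation protein, fell. POMP fell by 1.13 ± 0.09 in HCT116 and by 1.86 ± 0.09 in RKO. In HCT116 the median change of 31 subunit genes was 0.21 (11 rose and 0 fell, camera p = 6.4e-06, p = 0.22 with an estimated correlation). In RKO, where POMP fell more, the median of the same genes was 0.01 (1 rose and 2 fell, camera p = 0.89, p = 0.97 with an estimated correlation). The median difference, RKO minus HCT116, was -0.21 (0 higher and 5 lower, camera p = 7.0e-05, p = 0.28 with an estimated correlation). The prediction named both lines and was not met, because the subunit genes did not rise in RKO. The condition set in advance against the hypothesis also named both lines, and HCT116 did not meet it. A rise limited to HCT116 stays uncertain, since its call did not hold with an estimated correlation.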
